A study of Homo sapiens with 5 samples.

How the data were processed

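In situ Hi-C was measured in 5 libraries of RMG1 cells: 1 control (control hairpin), 2 ARID1A knockout (CRISPR) and 2 CAPH2 knockdown libraries, with groups and replicate numbers taken from the labels. Each deposited file holds a symmetric matrix of contact signal between bins of 1 Mb over the whole genome, 1 file per library. Reads were aligned with Bowtie2 to hg19, per the submitters' processing notes. The version of the aligner, the filters on read pairs and the program for binning and balancing are not given in the sources used here. The deposited signal is balanced within each library, as read from the values: the row sums of 94.9% to 96.5% of the measured bins lay within 0.1% of the library's median row sum, and the values are not whole. The common row sum differed between libraries, so signal was only used as shares or ratios within a library. Balancing removes differences in how many reads a bin yields, but it also acts on copy number, and contacts of a chromosome with others come out too low after a loss of copies and too high after a gain.

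A balanced value is a whole number of contacts times a factor for each of its 2 bins. These factors were estimated from low trans values, and the contacts recovered were whole within 0.05 for 98.5% to 99.2% of nonzero values in each library. Nearly all of the rest lay midway between whole numbers. Recovered totals were 58.4 M (megacontacts; control), 34.7 M and 35.7 M (KO) and 73.4 M and 112.3 M (KD), including contacts within a bin. Trans bin pairs without a contact made up from 5.61% (KD replicate 2) to 27.0% (KO replicate 2). Balancing the recovered contacts again returned the deposited signal within 2% for 95.5% to 96.7% of values. Neither check can show a bin factor too small by a whole divisor, since contacts stay whole and balancing takes the factor out. Recovered contacts of such bins would be too high. In a strong bin pair of chromosomes 9 and 11 they were 20 in the control and 232 and 280 in the KD libraries. In 3 of chromosomes 1 and 18 they were 2646, against 1190 and 1705. All results in recovered, unbalanced or thinned contacts carry this limit. Binomial intervals of shares were exact (Clopper-Pearson, 95%) and cover counting error only.

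Bins of chromosomes 1 to 22 and X present in all libraries were used (2811), and 38 with under 0.25 of the median total of the control were left out, leaving 2773. For each of 253 pairs of chromosomes the log2 of the summed signal over the product of the chromosomes' totals (scaled by the genome total) was taken. For each chromosome and 7 classes of distance (under 2 Mb, 2 to 5, 5 to 10, 10 to 20, 20 to 50, 50 to 100, and 100 Mb and over, without the same bin) the log2 share of its contacts between bins was taken. The trans share of a bin was log2 of (trans + 0.5) over (cis + 0.5) without the same bin, on the scale of the signal. Compartments were the first eigenvector of the correlation matrix of observed over expected signal per chromosome, scaled to an SD of 1. The sign in the control followed the trans share of its bins, and the sign in other libraries followed the control. Compartment strength was the mean observed over expected of A-A and B-B bin pairs over A-B pairs, between the outer 20% of bins by the control's eigenvector. Cell counts and depths were not used as covariates.

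The tests were planned for counts, with a limma test on log2 values where the files held none. Since the deposited signal is not counts, limma 3.58.1 (lmFit and eBayes, R 4.3.3) on log2 values was used for all families, with all 5 libraries in 1 fit. The control has 1 library, so its spread was taken from the KO and KD libraries, with 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg at 0.05, over all features of a family and comparison. Lists of chromosome pairs were tested with camera, with a preset and with an estimated correlation. The other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The limma steps for chromosome pairs, distance classes and trans share were tested on simulated data with the observed spread within KO and KD libraries. The control was given the mean SD of those groups. Noise was drawn separately for each feature, without the shifts that features of a library share. The simulated counts of false calls therefore do not show how many false calls the measured data hold. No more than 1 false call was made among 253 chromosome pairs (50 changed) or 2773 bins (200 changed; trans share) in any comparison. Of 149 distance classes (30 changed), 6 unchanged ones were called for KO against control and 4 for KO against KD, so calls of distance classes are less certain than their adjusted p. The groups differ in spread, which limma's shared variance does not model.

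The KD libraries were compared first with each other. Their bin totals differed by more than counting noise (chi-square per degree of freedom 17.8, and 360 between the KO libraries), which does not tell separate cultures from 2 preparations of 1 culture. Both were kept as replicates because the labels number them so, with an average of the 2 as an alternative. Pairs, classes and bins named in the text followed a rule fixed before the data were examined: the 5 largest rises and falls among chromosome pairs, 3 among distance classes and 10 among bins, of those past 0.05 that moved the same way in every replicate. Where none passed, the 3 with the smallest p are given and said not to pass. Groups of chromosomes were fixed at the same time.

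Alternatives fixed before the data were examined were other expectations, filters and pseudocounts, unbalanced contacts, quantile normalization, each replicate left out and the replicate number as a block. The alternatives with recovered contacts, averaged KD libraries, 2 Mb bins, pairs with chromosome 18 left out, other eigenvectors, thinning and crossed pairing were chosen after seeing the data. A planned trimmed scaling from a count package was replaced by a trimmed mean of log ratios (30% from each end). The insulation of domain borders was not run, since bins of 1 Mb are wider than the 100 kb it needs. The gene lists, and the bins holding ARID1A and NCAPH2, were not analysed, since the gene table at hand is of another genome build (GRCh38) than the files and coordinates were not converted. It was used for the number of genes on each chromosome, and places ARID1A on chromosome 1 and NCAPH2 on chromosome 22. Genes per bin and chromosome Y and mitochondrial bins did not enter any test.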

Results

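In situ Hi-C, which counts how often pieces of DNA lie close enough in the nucleus to be ligated to each other, was measured in RMG1 cells, an established human line of ovarian clear cell carcinoma. The labels give 5 libraries in 3 groups. A single control library came from cells with a control hairpin RNA and intact ARID1A and CAPH2. The ARID1A knockout group (ARID1A KO, made by CRISPR) and the CAPH2 knockdown group (CAPH2 KD, made with a hairpin RNA) had 2 libraries each. ARID1A is a DNA-binding subunit of the BAF chromatin remodelling complex, and CAPH2, now named NCAPH2, is a subunit of condensin II, a ring-shaped complex that compacts chromosomes. The title of the series asks how ARID1A bears on condensin II and on the partition of chromosomes. The numbers of contacts recovered from the balanced values were 58.4 M (megacontacts) for the control, 34.7 M and 35.7 M for the KO libraries, and 73.4 M and 112.3 M for the KD libraries. The bins were 1 Mb wide, so the state of the 2 target genes could not be checked in these files. The control shares its hairpin method with the KD group and not with the KO group, so the KO comparisons with the control and with the KD also compare methods. The labels do not say that replicates came from separate cultures or clones, so the p-values measure only the spread between these libraries, which may be technical.

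The first question was how contacts divided between and within chromosomes when ARID1A was absent. Contacts between different chromosomes (trans) made up 22.7% of the balanced signal in the control and 21.2% ± 0.466 (SD, n = 2) in the ARID1A KO libraries. The trans percent was below the control in both KO libraries for 22 of 23 chromosomes. Chance gives 33.3% for a single chromosome, but chromosomes of a library share its overall trans percent, so the count is no test. Chromosome 19 was the exception, at 41.4% in the control and 41.7% ± 1.30 (SD, n = 2) in the KO. In the balanced signal chromosome 18 differed most, at 33.9% in the control and 28.6% ± 0.761 (SD, n = 2) in the KO. These percents carry no test against a single control library. In the contacts recovered before balancing, 22.7% were trans in the control (cis 77.3%, exact binomial interval from 77.2% to 77.3%, counting error only) and 21.8% ± 0.414 (SD, n = 2) in the KO, and 17 of 23 chromosomes were lower in both libraries. There chromosome 22 differed most (47.2% and 41.6% ± 0.0103), chromosome 14 was higher in the KO (34.5% and 39.3% ± 0.400), and chromosome 18 differed little (40.4% and 39.3% ± 0.411; SD, n = 2 each). The lower trans percent of the KO depended on contacts within a bin, which were 45.3% of the balanced signal in the control and 49.3% ± 2.71 (SD, n = 2) in the KO. Without them the trans percent was 41.4% in the control and 41.0% and 42.8% in the 2 KO libraries, and in recovered contacts 42.7% against 43.4% and 45.5%.

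**Figure D1:**
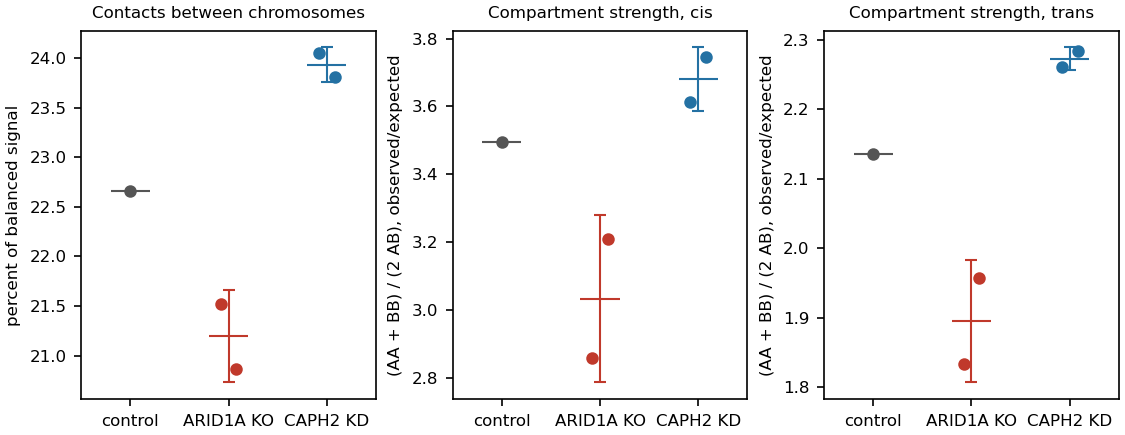
Each panel plots the 5 libraries as points by group, with the mean as a line and the SD between the 2 replicates as a bar for the KO and KD groups; the vertical axes do not start at 0. The panels show the trans percent of the balanced signal, the compartment strength within chromosomes and the compartment strength between chromosomes, with contacts within a bin counted in the trans percent, and in each the KO libraries lie below the control (22.7%, 3.495 and 2.14) and the KD libraries above it.

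Of 253 pairs of chromosomes, 12 fell in the ARID1A KO against the control and none rose (limma, Benjamini-Hochberg adjusted p under 0.05), and 77 had an unadjusted p under 0.05. The values are log2 of observed over expected contacts, with the expectation taken from the total contacts of both chromosomes, those within a bin included. Of the 12 pairs, 10 held chromosome 18, which is gene-poor. All 22 pairs with chromosome 18 were lower in both KO libraries, with a median log2 fold change of -0.24. The largest fall was between chromosomes 1 and 10, from -1.24 in the control to -1.83 ± 0.0125 (SD, n = 2), a log2 fold change of -0.59 (SE 0.025, limma adjusted p = 0.00194). Chromosomes 14 and 18 followed with -0.40 (SE 0.024, limma adjusted p = 0.00432). The next falls were -0.28 for chromosomes 15 and 18 and -0.27 for 5 and 18, both at a limma adjusted p of 0.0111, and -0.26 for 11 and 18 (limma adjusted p = 0.0203). In a simulation of this comparison with 253 pairs, 14 of 17 pairs given the smallest change simulated were called, and all 17 changed by 1.5-fold. Chromosome 18 also had fewer recovered contacts in the KO. The fall between chromosomes 1 and 10 shrank to -0.03 without bins within 20 Mb of 25 very strong bin pairs, but those bins enter 84.3% of bin pairs. With only the 33.5% of bin pairs near on both sides left out, the fall was still -0.35. In recovered contacts chromosomes 14 and 18 were higher in the KO (0.13), and with trans totals in the expectation the pair of 11 and 18 had a log2 fold change of 0.00. Of the 22 pairs with chromosome 18, 10 were higher and 12 lower in recovered contacts (median -0.04), and trans totals take out any change shared by the pairs of a chromosome. Pairs called were 105 (35 higher, 70 lower) when the recovered contacts replaced the balanced signal, 1 when the expectation used trans totals alone, 1 when pairs with chromosome 18 were left out, and 8, of which 3 were shared, when the KD libraries were averaged to 1 sample. Without KO replicate 1 the count was 192 and without replicate 2 it was 168, because the spread then came from the KD libraries alone, whose SD (0.0089) was far below that of the KO libraries (0.070).

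The 6 lists of pairs fixed before the data were examined divided in the KO as follows. Among the 63 pairs with the gene-poor chromosomes 4, 13 or 18, 10 fell over all pairs tested, all of them with chromosome 18, and 28 adjusted over the list alone, with a median log2 fold change of -0.12. This list lay below the other pairs by camera with a preset correlation (adjusted p = 1.92e-06), but not with an estimated one (adjusted p = 0.178 with an estimated correlation). In recovered contacts its median was 0.04 (14 higher and 6 lower called). The 25 pairs between the small gene-rich chromosomes 16, 17, 19, 20 and 22 and the large chromosomes 1 to 5 had a median of 0.01 and no call, 0 adjusted over the list alone, and camera placed them above the other pairs (adjusted p = 2.52e-05, and adjusted p = 0.178 with an estimated correlation). In recovered contacts 11 of them were called, 3 higher and 8 lower, and 11 over the list alone (median -0.05, camera adjusted p = 0.476). The 10 pairs within the small gene-rich chromosomes had a median of -0.08 and no call over all pairs or adjusted over the list alone (camera adjusted p = 0.213). In recovered contacts their median was -0.29, with 9 of 10 lower over all pairs and 10 adjusted over the list alone (camera adjusted p = 5.99e-04, and adjusted p = 0.611 with an estimated correlation). With trans totals it was -0.10, with 0 called over all pairs and 6 over the list alone (camera adjusted p = 3.40e-08, and adjusted p = 0.277 with an estimated correlation). Of the 10 pairs within the acrocentric chromosomes 13, 14, 15, 21 and 22, 1 fell over all pairs and 2 adjusted over the list alone (median -0.08, camera adjusted p = 0.213). Of the 22 pairs with the X, 1 fell and 1 did so adjusted over the list alone (median -0.03, camera adjusted p = 0.213). None of the 10 pairs within the large chromosomes was called by either adjustment (median -0.05, camera adjusted p = 0.365). In recovered contacts 3 acrocentric pairs were called higher and 3 lower, 2 pairs with the X higher and 3 lower, and 2 within large chromosomes higher.

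**Figure D2:**
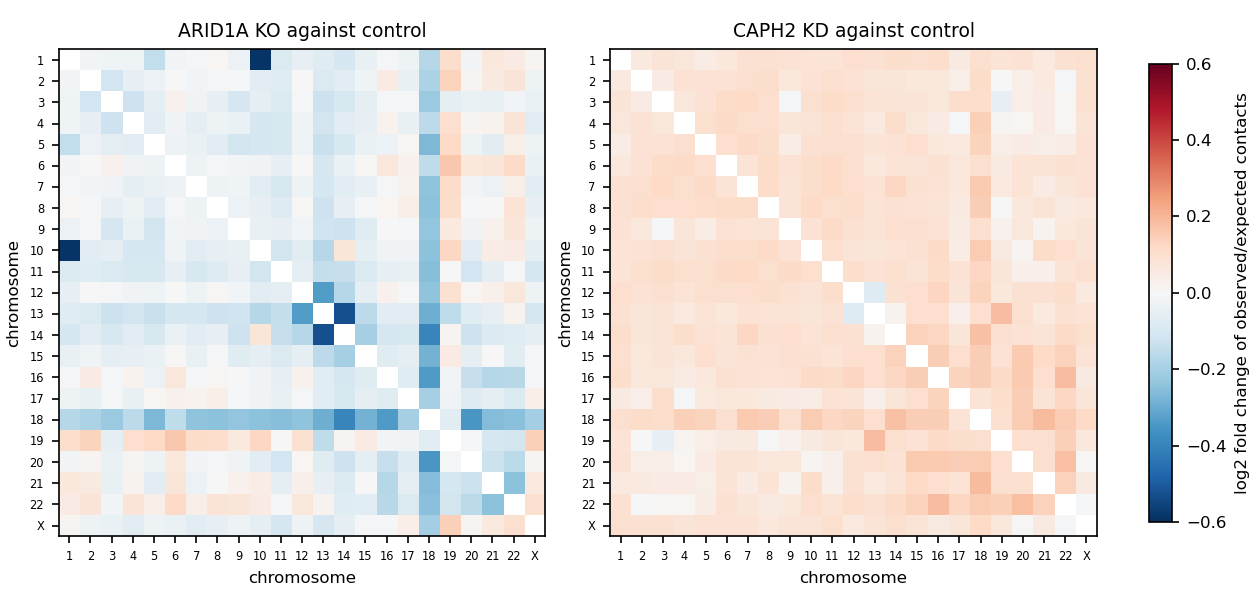
Each square is a pair of chromosomes, with the colour giving the log2 fold change of observed over expected contacts against the control, from -0.6 in blue to 0.6 in red, for ARID1A KO on the left and CAPH2 KD on the right. A blue row and column marks chromosome 18 in the KO (median -0.24 over 22 pairs) and a dark square chromosomes 1 and 10 (-0.59), while the KD map is mostly pale red (median 0.09 over 253 pairs).

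Within chromosomes, contacts at 20 to 50 Mb were lower in both KO libraries than in the control on all 23 chromosomes, with a median log2 fold change of -0.21. Chance gives 33.3% for a single chromosome, but chromosomes of a library are not independent, so such counts are no test. Contacts at 50 to 100 Mb were lower in both on 19 of 21 chromosomes (median -0.21), and those between neighbouring bins (under 2 Mb) were higher in both on 17 of 23 (median 0.06). In recovered contacts these counts were 20 of 23, 15 of 21 and 16 of 23. Their shares of contacts between bins of a chromosome were 12.6% in the control and 10.9% ± 0.413 (SD, n = 2) in the KO at 20 to 50 Mb. None of the 149 combinations of chromosome and distance class passed limma's test at an adjusted p of 0.05, and 34 had an unadjusted p under 0.05. The 3 with the smallest p, which do not pass, were chromosome 8 at 50 to 100 Mb (log2 fold change -0.24, SE 0.038), chromosome 2 at 20 to 50 Mb (-0.23, SE 0.037) and chromosome 18 at 50 to 100 Mb (-0.62, SE 0.10), each with a limma adjusted p of 0.129. When the class under 2 Mb was left out before totals were taken, 9 classes were called (1 higher, 8 lower), and without KO replicate 1 or 2 the counts were 126 (35 higher, 91 lower) and 132 (64 higher, 68 lower), with the spread again from the KD libraries alone.

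**Figure D3:**
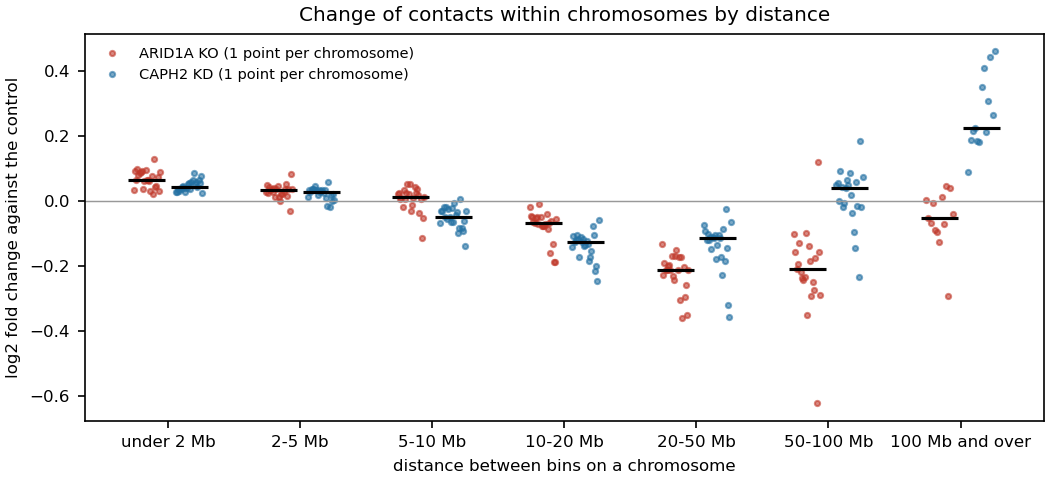
Points give the log2 fold change of the share of contacts within a chromosome against the control, 1 point per chromosome, in 7 classes of distance on the horizontal axis, with ARID1A KO in red and CAPH2 KD in blue and the median as a black line. At 20 to 50 Mb both groups lie below 0 (medians -0.21 and -0.11), and at 100 Mb and over the KD median is 0.23 against -0.05 for the KO.

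Compartments, the 2 classes into which chromosome regions separate (A, here the side with the higher trans share in the control, and B), had less contrast in the KO libraries. Compartment strength, the contacts of like bins over those of unlike bins, was 3.495 in the control and 3.03 ± 0.247 (SD, n = 2) in the KO within chromosomes. Between chromosomes it was 2.14 in the control and 1.90 ± 0.0886 (SD, n = 2) in the KO, but in unbalanced contacts this difference shrank to -0.043, with the KO libraries on both sides of the control (2.02 and 2.16 against 2.13). With each library's own eigenvector the difference within chromosomes was -0.18 in place of -0.46. In 54 of 2773 bins the compartment sign differed from the control in both KO libraries (14 from A to B and 40 from B to A, 1.95% of bins), while the 2 KO libraries differed from each other in 330 bins. On chromosome 5 the leading eigenvector of KO replicate 1 was unrelated to that of the control (r = 0.0029 across bins), and with the best-matching eigenvector 12 bins over all chromosomes went from A to B and 37 from B to A. No bin passed limma's test of the eigenvector, with 157 bins at an unadjusted p under 0.05. The 3 bins with the smallest p, none of which passes (limma adjusted p = 0.869 each), were on chromosome 2 from 189000001 to 190000000, chromosome 5 from 43000001 to 44000000 and chromosome 4 from 158000001 to 159000000 (hg19), with differences of 0.69, 0.72 and 0.68 in units of the SD per chromosome. From unbalanced contacts they were -2.57, 0.09 and 2.87, so the first turned. Eigenvectors from unbalanced contacts gave 1224 called bins, and leaving out KO replicate 1 or 2 gave 507 and 855.

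The trans share of single bins, log2 of trans over cis contacts, passed in no bin for ARID1A KO against control by limma, and 187 of 2773 bins had an unadjusted p under 0.05. The 3 bins with the smallest p, which do not pass (limma adjusted p = 0.689), were on chromosome 19 from 58000001 to 59000000 (log2 fold change 0.39, SE 0.061), chromosome 19 from 11000001 to 12000000 (0.35, SE 0.056) and chromosome 18 from 67000001 to 68000000 (-0.32, SE 0.056), in hg19. In recovered contacts the first was 0.28, and the other 2 turned, to -0.01 and 0.08. In simulated data of this comparison over 2773 bins, 61 of 66 bins changed by 2-fold and 24 of 67 changed by 1.5-fold were called. Without KO replicate 1 the median log2 fold change over all bins was 0.087 and without replicate 2 it was -0.011, so its direction depended on the library kept.

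The same measurements were then compared between the CAPH2 KD and the control, which addresses what lower condensin II does to contacts between chromosomes. The trans percent was 23.9% ± 0.174 (SD, n = 2) against 22.7% in the control, and it was above the control in both KD libraries on all 23 chromosomes. In the recovered contacts it was 23.5% ± 0.151 (SD, n = 2), and 17 chromosomes were higher and 6 lower in both libraries. Without contacts within a bin it was 44.0% and 44.1% against 41.4% in the balanced signal and 44.7% and 45.0% against 42.7% in recovered contacts. Of 253 pairs of chromosomes, 243 were higher than the control in both KD libraries and 5 were lower in both, with a median log2 fold change of 0.09. Chance gives 33.3% for a single pair, but pairs of a library are not independent. None passed limma's test at an adjusted p of 0.05, with a lowest adjusted p of 0.0788 and, in the balanced signal, 122 pairs at an unadjusted p under 0.05. With a scale per library, which takes out a shift common to all pairs, 10 pairs had an unadjusted p under 0.05, and with trans totals 13. The 3 pairs with the smallest p, which do not pass, were chromosomes 14 and 18 (log2 fold change 0.17, SE 0.024), 15 and 20 (0.16, SE 0.024) and 15 and 16 (0.15, SE 0.023). In simulated data of this comparison, with 253 pairs, all 17 pairs changed by 1.5-fold were called. The measured log2 fold changes ran from -0.078 to 0.189, and even the smallest change simulated was larger than these. That no pair passed therefore does not show that changes of the measured size were absent. With recovered contacts in place of the balanced signal 149 pairs were called, 125 higher and 24 lower, with the same limit from read yield and bin factors.

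By the fixed lists, the 10 pairs within small gene-rich chromosomes had the highest median in the KD, 0.14, with no call over all pairs and 10 adjusted over the list alone. Camera placed them above the other pairs (adjusted p = 0.00463, and adjusted p = 0.793 with an estimated correlation). The 25 pairs of small gene-rich with large chromosomes had the lowest median in the balanced signal, 0.05, with no call over all pairs or over the list alone, and lay below the other pairs (camera adjusted p = 1.72e-05, and adjusted p = 0.323 with an estimated correlation). The acrocentric list had a median of 0.11 and 6 of 10 pairs called adjusted over the list alone (camera adjusted p = 0.927). No pair of the other 3 lists was called by either adjustment. Their medians were 0.07 within large chromosomes (camera adjusted p = 0.594), 0.08 with the X (0.343) and 0.09 with chromosome 4, 13 or 18 (0.594). In recovered contacts the order was another, with 0.27 within small gene-rich (8 called, all higher), 0.13 for small gene-rich with large (13 higher, 1 lower) and 0.05 with chromosome 4, 13 or 18 (24 higher, 18 lower). There the acrocentric list had 2 pairs called higher and 3 lower, the large list 7 higher, and the X 13 higher and 2 lower. With trans totals no pair of any list was called, over all pairs or over a list alone.

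Within chromosomes, the longest contacts, at 100 Mb and over, were higher in both KD libraries on all 13 chromosomes long enough to have them (median log2 fold change 0.23). They made up 2.30% of contacts between bins of a chromosome against 2.00% in the control, and in recovered contacts 2.21% ± 0.00550 (SD, n = 2) against 2.09%, with 12 chromosomes higher and 1 lower. Contacts at 10 to 20 Mb and at 20 to 50 Mb were lower in both KD libraries on all 23 chromosomes (medians -0.13 and -0.11), and neighbouring bins were higher on all 23 (median 0.04). In recovered contacts these counts were 21, 20 and 21 of 23. None of the 149 classes passed limma's test, and 21 had an unadjusted p under 0.05. The 3 with the smallest p, which do not pass, were at 100 Mb and over on chromosome 12 (log2 fold change 0.26, SE 0.037), chromosome 10 (0.31, SE 0.043) and chromosome 4 (0.23, SE 0.041). The limma adjusted p was 0.146 for chromosomes 12 and 10 and 0.168 for chromosome 4. When the class under 2 Mb was left out, 2 classes were called, both higher.

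Compartment strength in the KD was 3.68 ± 0.0942 (SD, n = 2) within chromosomes against 3.495 in the control, and 2.27 ± 0.0163 (SD, n = 2) between chromosomes against 2.14. The compartment sign differed from the control in both KD libraries in 70 bins (25 from A to B and 45 from B to A, 2.52% of 2773), and the 2 KD libraries differed from each other in 46. By limma no bin passed in the compartment test (42 at an unadjusted p under 0.05) or the trans-share test (578). The compartment bins with the smallest p, which do not pass (limma adjusted p = 0.999), were on chromosome 18 from 43000001 to 44000000 and from 42000001 to 43000000 and on chromosome 4 from 20000001 to 21000000 (hg19), with differences of -0.77, -0.70 and -0.41. The trans-share bins with the smallest p, which do not pass either (limma adjusted p = 0.216), were on chromosome 4 from 45000001 to 46000000 and from 43000001 to 44000000 and on chromosome 14 from 25000001 to 26000000, with log2 fold changes of 0.35, 0.32 and 0.32. In simulated data of this comparison 53 of 66 bins changed by 2-fold in trans share were called, and 34 of 67 changed by 1.5-fold. Of 67 bins given the smallest change simulated, 0 were called. The median log2 fold change of trans share over all measured bins was 0.16. That no bin passed therefore does not show that small changes in trans share were absent. Eigenvectors from unbalanced contacts gave 418 called bins.

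The comparison of the ARID1A KO with the CAPH2 KD asked whether loss of the remodeller and depletion of the condensin subunit gave the same contacts. It was the only comparison with replicates on both sides, but it also set CRISPR cells against hairpin cells. Differences of the KO cells from the control, such as the lower chromosome 18 pairs, enter it too. The trans percent was 21.2% ± 0.466 in the KO and 23.9% ± 0.174 in the KD (SD, n = 2 each), and 2 against 2 libraries cannot give an exact permutation p below 0.333. In recovered contacts without those within a bin, the groups came close (43.4% and 45.5% in the KO, 44.7% and 45.0% in the KD). Between the groups 182 of 253 pairs of chromosomes differed by limma, 178 lower and 4 higher in the KO. The totals in the expectation include contacts within a bin, which were 49.3% of the balanced signal in the KO and 45.7% in the KD. A higher share of these lowers the values of pairs, and no setting left out only them. The falls therefore do not by themselves show fewer contacts between chromosomes. All 10 pairs within the small gene-rich chromosomes 16, 17, 19, 20 and 22 were lower in the KO, over all pairs and adjusted over the list alone, with a median of -0.22. As a list they did not pass camera (adjusted p = 0.059, and adjusted p = 0.661 with an estimated correlation). With recovered contacts this list had a median of -0.54 and 10 called pairs (camera adjusted p = 0.0063, and adjusted p = 0.582 with an estimated correlation). With trans totals in the expectation it had -0.16 and 7 (4.32e-09 and 0.162).

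The largest falls from KD to KO were between chromosomes 1 and 10 (log2 fold change -0.67, SE 0.021, limma adjusted p = 3.50e-04) and 14 and 18 (-0.57, SE 0.019, the same adjusted p). Next came 18 and 20 (-0.50), 16 and 18 (-0.49) and 18 and 21 (-0.45), and all 22 pairs with chromosome 18 fell. In recovered contacts 16 of these were called lower and 1 higher, and with trans totals none was called. The 4 pairs that were higher in the KO were 2 and 19 (0.13), 22 and X (0.10), 8 and 19 (0.10) and 2 and 22 (0.09), with limma adjusted p from 0.0166 to 0.0450. In recovered contacts all 4 of these were lower in the KO. With the replicate number as a block, 1 pair was called higher and 149 lower. In simulated data of this comparison over 253 pairs, all 17 pairs changed by 1.5-fold were called, with 1 false call. The median over all pairs was -0.13, and a scale per library, which brings it to 0.00, gave 63 pairs (31 higher, 32 lower), of which 36 were among the 182. The count was 25 (12 higher, 13 lower) with trans totals, 37 with the KD libraries averaged, 36 without KD replicate 1 and 37 without KD replicate 2. With pairs of chromosome 18 left out, 161 of 231 pairs were called, 4 higher and 157 lower.

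Of the other lists, 52 of 63 pairs with chromosome 4, 13 or 18 were lower in the KO than in the KD and 54 differed adjusted over the list alone (median -0.19, camera adjusted p = 0.0208, and adjusted p = 0.364 with an estimated correlation). In recovered contacts 26 of them were higher and 26 lower (median -0.04), and with trans totals 4 were higher and 0 lower. Of the 25 pairs between small gene-rich and large chromosomes, 9 were called, 7 lower and 2 higher, and 4 adjusted over the list alone. Their median was -0.03, and camera placed them above the other pairs although the median was negative (adjusted p = 1.83e-07, and adjusted p = 0.232 with an estimated correlation). With trans totals 6 of them were called, all higher (median 0.05), and in recovered contacts 3 higher and 15 lower (median -0.17). Lower in the KO were 9 of 10 pairs within large chromosomes (9 adjusted over the list alone, camera adjusted p = 0.433) and 7 of 10 acrocentric pairs (7 adjusted over the list alone, camera adjusted p = 0.359). With the X, 12 pairs were lower and 1 higher (11 adjusted over the list alone, camera adjusted p = 0.167). In recovered contacts 7 pairs within large chromosomes were lower, 4 acrocentric pairs were higher and 5 lower, and 3 pairs with the X were higher and 13 lower. With trans totals 0 large, 0 acrocentric and 1 X pair (higher) were called.

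Of 149 distance classes 16 differed between KO and KD by limma, all lower in the KO, of which 9 were at 100 Mb and over, 6 at 50 to 100 Mb and 1 at 20 to 50 Mb. Contacts at 100 Mb and over were lower in every KO library than in every KD library on all 13 chromosomes (median -0.28). Chance gives 16.7% for a single chromosome, and chromosomes are not independent. The largest falls were on chromosome 11 at 100 Mb and over (log2 fold change -0.73, SE 0.13, limma adjusted p = 0.0491), on the X at 100 Mb and over (-0.50, SE 0.090, limma adjusted p = 0.0491) and on chromosome 11 at 50 to 100 Mb (-0.44, SE 0.066, limma adjusted p = 0.0391). No class was called with recovered contacts. There contacts at 100 Mb and over were lower in the KO on 12 of 13 chromosomes and higher on 1 (median -0.19), but the shares over all chromosomes overlapped (2.06% and 2.22% in the KO, 2.21% and 2.22% in the KD). The count was 9 with a scale per library, 51 without the class under 2 Mb (23 higher, 28 lower), 4 with the KD libraries averaged, and 4 and 5 without KD replicate 1 and 2. Without KO replicate 1 it was 127 (42 higher, 85 lower) and without replicate 2 it was 130 (70 higher, 60 lower).

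Compartment strength was lower in the KO than in the KD by 0.65 within chromosomes (3.03 ± 0.247 against 3.68 ± 0.0942, SD, n = 2 each). Between chromosomes the means were 1.90 ± 0.0886 and 2.27 ± 0.0163 (SD, n = 2 each). In unbalanced contacts the difference between chromosomes was -0.19 in place of -0.38 (2.02 and 2.16 in the KO, 2.26 and 2.30 in the KD). Limma called no bin in the compartment test (303 of 2773 at an unadjusted p under 0.05) and none in the trans-share test (871). The trans-share bins with the smallest p, which do not pass (limma adjusted p = 0.0737), were on chromosome 18 from 27000001 to 28000000 and from 24000001 to 25000000 and on chromosome 10 from 83000001 to 84000000 (hg19). Their log2 fold changes were -0.53, -0.51 and -0.54, and in recovered contacts -0.20, -0.19 and 0.12, so the third turned. In the compartment test they were on chromosome 5 from 43000001 to 44000000, chromosome 2 from 153000001 to 154000000 and chromosome 3 from 139000001 to 140000000, with differences of 0.87, 0.94 and -0.98 (limma adjusted p = 0.357, not passing). From unbalanced contacts they were 0.18, -3.07 and -0.22, so the second turned. The trans-share test gave 594 bins with recovered contacts. In the compartment test 1383 bins were called from unbalanced contacts, and without KO replicate 1 or 2 the counts were 730 and 1195 there and 1957 and 2417 for the trans share.

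Both comparisons with the control share that single library, which by itself gives a positive correlation of their fold changes. Across the 253 chromosome pairs, which are not independent of each other, the log2 fold changes of KO and KD against the control had a correlation of -0.36, where simulated unchanged groups gave 0.66. The covariance was -0.00136 against a simulated 0.00256, a difference of -0.00392. The 22 pairs with chromosome 18 had medians of -0.24 in the KO and 0.13 in the KD, against -0.04 and 0.09 for the other 231. They add to the negative values, and no correlation was computed without them. The correlation over pairs therefore does not show opposite changes across all chromosomes. For the compartment eigenvector across 2773 bins the correlation was 0.28 against 0.67 simulated, and for the trans share of bins 0.16 against 0.67. Their covariances lay below the simulated ones by 0.0637 and 0.0100. Of the bins that switched compartment sign in both replicates, 16 were shared by KO and KD, where independent lists give 1.36. The lists are not independent, since both rest on the signs of the single control, which could not be split. Switched bins lay near 0 in the control (median absolute value 0.126 for KO and 0.0926 for KD, in units of the SD). There a small error of the control turns the sign in both lists, so the excess is no sign of a shared response.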

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

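The tests of trans to cis changes, of random ligation, by balancing again, by thinning and without the neighbourhood of strong bin pairs were all chosen after the patterns were seen, the last 3 before their own values were computed. Recovered contacts per bin, which no comparison used, were above the control in both ARID1A KO libraries by over 0.3 (median log2 per chromosome, against the median of the library) on 3 chromosomes. The mean was 0.36 on chromosome 17, 0.458 on chromosome 19 and 0.486 on chromosome 22, and no chromosome met this in the CAPH2 KD. Chromosomes 13 and 18 were below the control by over 0.3 in both KO libraries, at -0.0862 and 0.215 against 0.525 on chromosome 13 and -1.05 and -1.12 against -0.440 on chromosome 18.

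The first pattern weighed is the fall of chromosome 18 pairs in the ARID1A KO. Recovered contacts within chromosome 18 fell by 1.15 times as much, on the log2 scale, as its contacts with other chromosomes (1.145 and 1.134 in the 2 KO libraries), which argues against fewer reads alone, since those would give a ratio near 2. Scaling the recovered chromosome 18 contacts of the control by 0.708, the change seen in the KO, and balancing again lowered the median chromosome 18 pair by -0.213, against -0.244 observed, so a lower copy number acted on by balancing may account for most of the fall. The change from the control of the trans to cis ratio of chromosome 18 in recovered contacts was 0.0689 (log2) in the lower KO library. It was taken relative to the median changes of trans and of cis contacts over chromosomes, without contacts within a bin. Fewer contacts of each copy with other chromosomes cannot be told apart from that, because a lower read yield together with a true loss of trans contacts would leave the same ratio.

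The second pattern is the order of compartment strength, lowest in the KO and highest in the KD. After all libraries were thinned to the same number of contacts (34.5 M, megacontacts) and balanced again, the gap between KO and KD kept 100.1% of its size between chromosomes and 101.2% within them, which argues against depth. Random ligation would move trans percent and strength in opposite ways. In the KD both were above the control in 16 of 16 comparisons (balanced and recovered, with and without contacts within a bin). The comparisons are not independent, since they reuse the 2 libraries of a group, the single control library and the same values. The count is therefore no test, but the shared direction in both KD libraries argues against random ligation alone for the higher strength there. Less random ligation together with a true rise of trans contacts would give the same direction, and this cannot be told apart. For the lower strength in the KO random ligation cannot be told apart from other causes. There trans percent and strength moved the same way in only 10 of 16 comparisons. Without contacts within a bin trans percent was higher in KO replicate 2 (42.8% against 41.4%). The loss of ARID1A and the depletion of CAPH2, which the design names, stay open and untested, as does the difference between CRISPR and hairpin cells, and in unbalanced contacts the KO difference between chromosomes was only -0.0433 (2.02 and 2.16 against 2.13).

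The third pattern is the fall of the chromosome 1 to 10 pair in the KO. Strong bin pairs between these chromosomes held 0.0272% of trans contacts in the control, 0.00228% and 0.00306% in the KO libraries and 0.0178% and 0.0161% in the KD libraries. Without all bins within 20 Mb of them, which leaves out 84.3% of bin pairs, the log2 fold change went from -0.59 to -0.0266 (0.034 and -0.087 in the KO libraries), so a join of the chromosomes that is absent or rarer in the KO cells is a candidate explanation. A less strict version, run first by mistake, left out the 33.5% of bin pairs with both bins near and gave -0.35, and without the strong bin pairs alone the fall stayed at -0.58 (limma adjusted p = 0.00132). Any difference spread over those regions would end with them too, and no biological explanation was tested.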

How the results depend on the processing

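Alternatives with recovered contacts, averaged KD libraries, crossed pairing, thinning to the same depth, matched eigenvectors and pairs with chromosome 18 left out were chosen after seeing the data, as were all those of the lists and the left-out replicates of the library values. Insulation was not run, the 1 Mb bin size was already that of the files, and DESeq2 was not run because the signal is not counts. Unless a cause is given with a value, the cause was not tested.

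With recovered contacts in place of the signal, chromosome pairs called were 105 for KO against control and 149 for KD against control, distance classes for KO against KD 0, and trans-share bins for KO against KD 594. With trans totals the pairs were 1 (KO against control) and 25 (KO against KD), with a scale per library 63 pairs and 9 distance classes (KO against KD), and without chromosome 18 pairs 1 (KO against control). Averaging the KD libraries gave 37 pairs and 4 distance classes for KO against KD and 1 class for KO against control. Leaving out the class under 2 Mb gave 9, 2 and 51 classes in the 3 comparisons, and unbalanced contacts 1224, 418 and 1383 compartment bins. With the replicate number as a block, 150 pairs, 22 distance classes, 0 compartment bins and 101 trans-share bins were called for KO against KD. Deviations of the same number correlated at 0.06, -0.24, -0.10 and 0.038 for pairs, classes, compartments and trans share, so the numbers were not taken to pair the libraries. Crossed pairing, which the numbers do not give, called 149 pairs, 24 classes, 0 compartment bins and 246 trans-share bins, so the gain of trans-share bins with a block does not rest on the numbers.

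Leaving out a KO replicate leaves the spread to the KD libraries, and the lone sample is assumed to vary like them. The counts without a replicate ranged from 168 to 192 (pairs), 126 to 132 (classes), 1494 to 1948 (trans share) and 507 to 855 (compartments) for KO against control. For KO against KD they ranged from 36 to 237, 4 to 130, 0 to 2417 and 0 to 1195. For KD against control they were 0 throughout.

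The KO minus control difference in cis percent was 1.46 points, and -0.456 without same-bin contacts and 0.931 with recovered contacts. For the KD it was -1.27, and -2.64 and -0.752. Compartment strength, -0.462 in the KO, was -0.753 with the outer 10% of bins, -0.178 with each library's own eigenvector and -0.176 with the matched one. The KO libraries were at 2.86 and 3.21 against 3.495 in the control, so the size of the difference depended on the replicate. Between chromosomes the KO difference was -0.241, and -0.0433 unbalanced and -0.34 with the outer 10% of bins. For the KD it was 0.137, and 0.176 with the outer 10% of bins and 0.187 with own and with matched eigenvectors. The correlation of KO and KD changes was -0.359 over pairs (those with chromosome 18 included), 0.278 over compartment bins and 0.162 over trans share.

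Directions that turned with recovered contacts were 14 with 18 (0.132, KO against control), 2 with 19 (-0.0733), 22 with X (-0.134), 8 with 19 (-0.194) and 2 with 22 (-0.105), all KO against KD. The trans-share bins at 11 Mb on chromosome 19 (-0.0133), 67 Mb on 18 (0.0843) and 83 Mb on 10 (0.119) turned too. With trans totals 11 with 18 was 0.00348. With unbalanced contacts the compartment bins of chromosome 2 starting at 189000001 and 153000001 were -2.57 and -3.07. Medians of lists that turned with recovered contacts (KO against control) were 0.0316 within large, -0.0549 for small gene-rich with large and 0.0359 with 4, 13 or 18. With trans totals they were 0.00355 within large, 0.00967 with X and 0.00612 with 4, 13 or 18 for KO against control, -0.0259 for small gene-rich with large and -0.00122 with X for KD against control, and 0.0525, 0.014 and 0.0138 for small gene-rich with large, with X and with 4, 13 or 18 for KO against KD. Of 390 alternatives of the 44 named pairs, classes and bins, 305 kept direction and side of the threshold. Most of the 44 did not pass in the main setting, and for those, keeping the side only means that they still did not pass. Thinned to the same depth, the libraries kept strengths and cis percent within the spread between replicates.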

Other observations

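The tests behind these values were chosen after the data were seen. Of the row sums of the balanced signal, trans contacts of A bins were 32.0% in the control, 31.4% ± 0.0881 (SD, n = 2) in the ARID1A KO and 33.6% ± 0.14 (SD, n = 2) in the CAPH2 KD. In B bins they were 27.4%, 25.9% ± 0.128 and 29.2% ± 0.132 in the same order. In recovered contacts the KO differed more in A bins than in B bins, with A bins at 31.3% in the control and 30.3% ± 0.00127 in the KO and B bins at 28.4% and 28.2% ± 0.0856 (SD, n = 2 each). Contacts within a bin count in these percents. Without them the median log2 of trans over cis was -0.15 in the control, -0.17 and -0.01 in the KO libraries and 0.01 and 0.02 in the KD libraries in A bins. In B bins it was -0.77, -0.83 and -0.74, and -0.61 and -0.60, so in both classes the KO libraries lay on both sides of the control. Contacts between B bins of different chromosomes, as observed over expected, were 1.10 in the control, 1.01 ± 0.011 in the KO and 1.17 ± 0.0057 in the KD (SD, n = 2 each). Contacts between A bins were 1.75, 1.72 ± 0.0163 and 1.75 ± 0.000424. In unbalanced contacts those between A bins were higher in the KO, at 1.79, 2.11 ± 0.00422 and 1.78 ± 0.0367, and those between B bins differed more, at 1.05, 0.694 ± 0.00549 and 1.19 ± 0.0244 (SD, n = 2). Unbalanced values also carry differences in how many reads a bin yields, so they do not by themselves show more contacts between A bins in the KO.

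Other strong trans bin pairs also differed between libraries, including the 2 KO libraries. Those between chromosomes 13 and 14 held 0.198% of trans contacts in the control, 0.00962% in KO replicate 1, 0.0867% in KO replicate 2, and 0.215% and 0.214% in the KD libraries. Those between chromosomes 11 and 20 held 0.00240% in KO replicate 1 and 0.0421% in KO replicate 2, against 0.0197% in the control. The pair of chromosomes 13 and 14 had a log2 fold change of -0.53 in the KO against the control (SE 0.30, limma adjusted p = 0.291, not passing), with the 2 KO libraries at -1.59 and -0.86 against -0.70.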
